A study of Mus musculus with 4 samples.

How the data were processed

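The study isolated covalent TopoIIa-DNA complexes with an anti-V5 antibody from sonicated mouse embryonic stem cells after a 10 min exposure to 100 µM etoposide, per the labels' protocols. The libraries were amplified for 17 cycles and selected at about 300 bp before sequencing on a Solexa instrument, per the labels' protocols. The cells had been grown on embryonic fibroblast feeders and were moved to gelatin for the tamoxifen or ethanol treatment, per the labels' protocols. A protocol of this kind marks only enzyme caught on DNA during the drug pulse.

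For each V5 library the authors deposited 1 list of peaks with chromosome, start, end, a peak name and a score. Bowtie 0.12.8, MACS 1.4.2 and the build mm9 are named per the submitters' processing notes, which give no roles, and the peak names in the files carry the MACS prefix. The deposited score has no header. Its lowest values, 50 and 50.02, match the scale of −10 times the log10 of a p-value with a limit at 1e-05, which MACS uses. The scores were used here only to rank or filter peaks. Filters used the same limits in both lists, although a given score need not mean the same in each. The filters, the control used in calling, the fragment size and the handling of reads that map to several places are not given in the sources used here. Each list belongs to 1 library, so the peaks appear to have been called per library. No peak overlapped another peak of its own list.

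Groups were taken from the sample titles: wild-type V5, knockout V5 and the 2 inputs. The inputs have labels but were not analysed here. Positions were kept in mm9 and are printed 1-based. The only reference given was a gene table of the assembly GRCm38.p6, another build, so peaks were not assigned to genes or promoters. The comparisons of promoter share and of the 11 gene lists fixed beforehand were for that reason not run, and no gene is named.

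A peak was called shared when it overlapped a peak of the other list by at least 1 bp. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only and treat peaks as independent. Chance overlap was taken from 1000 random placements of the knockout peaks between the first and the last called position of their own chromosome, widths kept, and from 1000 moves of each knockout peak by 100 to 1000 kb in either direction. The 50 placements used for centre positions and the 100 used for groups of peaks were drawn in the same way. Random placement ignores unmappable sequence, so it gives a rough floor. Bins of score hold equal numbers of peaks. Named peaks followed a rule written before the data were examined: the 10 highest-scoring peaks of each list, the 10 highest-scoring wild-type peaks and the 5 highest-scoring knockout peaks without a peak of the other list within 1 kb, with ties broken by width. The groups of knockout peaks, the fixed widths of 2 kb and 500 bp and the pooling of the autosomes for comparison with X were chosen after seeing the data, while the shared share of each chromosome was planned.

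The overlap script was tested on simulated data. In 4 simulated knockout lists of 4622 peaks, with a known share placed on wild-type peak centres, the recovered share differed from the planted one plus chance by at most 0.207 percentage points. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. With 1 library per genotype, no replicate could be left out. The alternatives tried were other score limits, other definitions of a shared peak, merged peaks, chromosomes 1 to 19 and X only, peaks up to 5 kb, other bins and other rankings.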

Results

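Sites of topoisomerase IIα (TopoIIa) activity were mapped in mouse embryonic stem cells with and without Brg1, the ATPase of the BAF (mSWI/SNF) chromatin remodelling complex. TopoIIa is the enzyme that passes one DNA duplex through another and thereby separates intertwined DNA. Etoposide, a topoisomerase II poison, holds the enzyme on the DNA it has cut, so that a pull-down of the enzyme marks where it was working. The cells carried a V5-tagged human TopoIIa in place of the mouse enzyme, which was knocked down, and a Brg1 allele that tamoxifen-activated Cre deletes. Tamoxifen gave the Brg1 knockout and ethanol the wild-type control, each for 24 h followed by 48 h of recovery, and 100 µM etoposide was present for the last 10 min. The series held 4 samples, a V5 chromatin immunoprecipitation and an input from each genotype, with 1 library per group. The values below come from the peak list of each V5 library, and the reads and the inputs were not analysed here. The depth of the libraries is therefore unknown. With 1 library per genotype there was no replicate error, and no p-value between genotypes was computed. Neither list measures Brg1, so the genotype of each library rests on its label.

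The first comparison asked how many sites of TopoIIa activity were called in each genotype. The wild-type list held 16591 peaks and the knockout list 4622, so that 3.59 times as many peaks were called with Brg1 as without it. The score is the authors' own for each peak and is comparable only within its list. Its median was 105.95 in the wild-type list (interquartile range 70.0 to 180.48, lowest 50) and 58.2 in the knockout list (54.2 to 66.8, lowest 50.02). At a score of at least 100 the wild-type list kept 8818 peaks (53.1%) and the knockout list 353 (7.64%).

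The peaks of the 2 lists differed in width as well as in number. The median wild-type peak was 2158 bp wide (interquartile range 1804.5 to 2566 bp), and the median knockout peak was 141 bp wide (129 to 162 bp), a ratio of 15.3. The narrowest wild-type peak measured 581 bp, and 98.5% of knockout peaks (4554) were narrower than that. The wild-type peaks covered 38.9 Mb at a mean width of 2342 bp and the knockout peaks 0.811 Mb at a mean of 175 bp. The total length thus differed 47.9 times, more than the number of peaks. Both libraries were selected at about 300 bp, which is above the median width of the knockout peaks and below that of the narrowest wild-type peak. The settings of the peak caller, which act on peak width, score and number, are not given in the sources used here. Whether both lists were called in the same way is therefore unknown. The ratios of number, width and total length may reflect the calling as well as the genotype.

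**Figure D1:**
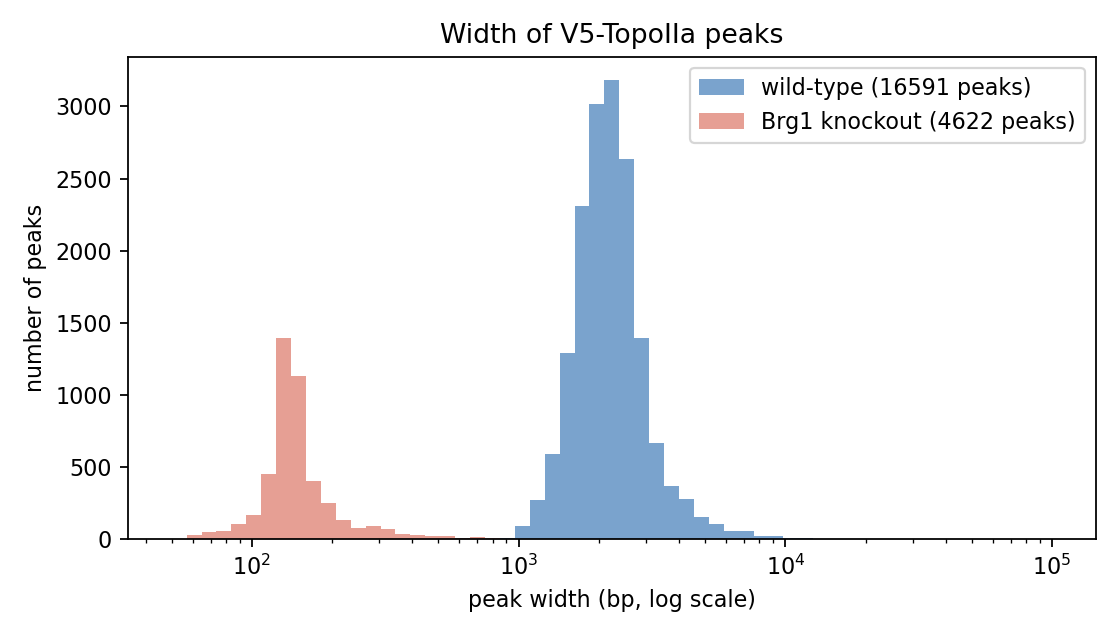
Number of peaks (vertical axis) by peak width in bp (horizontal axis, log scale) in the wild-type list (blue) and the Brg1 knockout list (red). The 2 distributions hardly meet: the medians are 2158 bp and 141 bp.

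The second comparison asked which sites were found in both genotypes. Of the 16591 wild-type peaks, 818 (4.93%, exact 95% interval 4.61 to 5.27%) overlapped a knockout peak by at least 1 bp, and 15773 (95.1%) did not. Of the 4622 knockout peaks, 982 (21.2%, 20.1 to 22.5%) overlapped a wild-type peak and 3640 did not. These intervals cover counting error only. The shared sites lay well above chance: when the knockout peaks were placed at random within their own chromosomes 1000 times, a mean of 74.3 wild-type peaks (0.448%) and at most 103 were hit, so the observed number was 11.01 times the mean. Moving each knockout peak by 100 to 1000 kb instead gave a mean of 77.7. Neither placement separates shared TopoIIa sites from positions that collect reads in any library, since the inputs were not used. A wider search found 870 wild-type peaks (5.24%) with a knockout peak within 1 kb, against a mean of 132.8 after random placement, so the excess over chance fell to 6.55 times. Requiring an overlap of 50% of both peaks left 2 pairs, which the unequal widths alone make rare.

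Where the lists met on wild-type peaks of at most 5 kb, they met near the middle of the wild-type peak. Among the 814 knockout peaks that lay on such a peak, 453 (55.7%, exact 95% interval 52.2 to 59.1%) had their centre in the central 25% of its width. Randomly placed knockout peaks that fell on such wild-type peaks did so in 23.8% of cases. On wider wild-type peaks 49 of 168 knockout peaks (29.2%, 22.4 to 36.7%) were central, against 25.4% after random placement, within the counting error. Most shared wild-type peaks (771 of 818) held 1 knockout peak, and 47 held more, up to 59.

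Wild-type peaks of higher score more often had a knockout peak, with small dips in bins 3 and 5. In the lowest of 10 equal bins of wild-type score 19 of 1660 peaks (1.14%, exact 95% interval 0.690 to 1.78%) were shared, and in the highest bin 194 of 1659 (11.7%, 10.2 to 13.3%). Random placement gave 0.340% and 0.666% in these bins, a smaller step than observed. With every peak set to 2 kb the shares were 1.33% and 11.6%. The median score was 174.82 for shared and 103.59 for unshared wild-type peaks. Even so, most of the top-scoring wild-type sites had no knockout peak: 73 of the 100 highest-scoring peaks were unshared. In the knockout list the share stayed between 11.4% and 18.2% in bins 1 to 7, with bin 2 (17.1%) above bins 3 to 6, and then rose to 23.6%, 31.8% and 53.2% (48.6 to 57.9%) in bins 8 to 10.

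**Figure D2:**
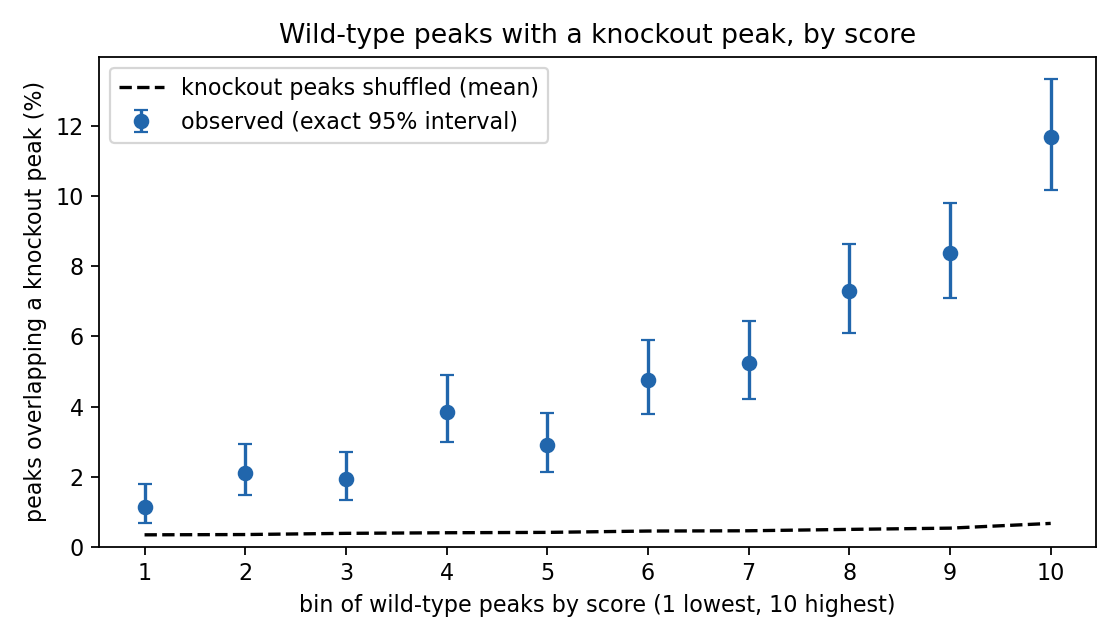
Share of wild-type peaks that overlap a knockout peak, in percent, in 10 equal bins of wild-type score (1 lowest, 10 highest). Points are observed shares with exact 95% intervals, from 1.14% to 11.7%, and the dashed line is the mean after random placement of the knockout peaks.

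Because list length moves with the threshold and with depth, the lists were also compared at equal length. Of the 4622 top-scoring wild-type peaks, as many as the knockout list holds, 426 (9.22%, exact 95% interval 8.40 to 10.1%) overlapped a knockout peak, against a mean of 26.4 after random placement. In the top 1000 of each list 83 wild-type peaks (8.3%) were shared.

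Named sites were taken by score, and are given by position in mm9, since no annotation of that build was used here. The top-scoring wild-type site lay on chromosome 14 from 21072001 to 21077397 (5397 bp, score 3233.06), and the nearest knockout peak was 22.4 kb away. The next lay on chromosome 13 from 6604114 to 6613238 (9125 bp, score 3109.65), 54.5 kb from the nearest knockout peak. A further 26 wild-type peaks shared the score 3100, as did the top knockout peak. Their order carries no information, and whether they truly rank below the sites on chromosomes 14 and 13 is unknown. Of the 28 wild-type peaks that scored 3100 or more 12 had a knockout peak (42.9%, exact 95% interval 24.5 to 62.8%). One was the site on chromosome 17 from 39978571 to 39987150, where the knockout list had its own top peak, from 39979921 to 39985842 (score 3100). The 10 top wild-type sites with no knockout peak within 1 kb lay on 8 chromosomes, all scored 3100 or more, and were 4631 to 18429 bp wide. They included chromosome 3 from 93006417 to 93024845, X from 131574601 to 131592208 and chromosome 8 from 12129657 to 12135591.

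Of the 10 top knockout peaks, 8 lay on a wild-type peak. Neither the inputs nor the mm9 sequence were used here, so whether these positions also collect reads without TopoIIa, as repeated sequence can, is unknown. Several of these, on chromosome 2 between 98502366 and 98507510, fell within a single wild-type peak from 98501472 to 98508915 (score 2129.64). Others were on chromosome 4 from 118219636 to 118221375 (score 2000.49), inside a wild-type peak with a score of 3100, and on chromosome 17 from 13743505 to 13746071 (score 1859.81). The top knockout peaks with no wild-type peak within 1 kb lay on chromosome 17 from 4626116 to 4626591 (score 634.76) and on chromosome 15 from 74916668 to 74917490 (score 605.66). The nearest wild-type peaks were 358 kb and 80.1 kb away. The next peaks under this rule, on chromosomes 12, 6 and 2, lay nearer to a wild-type peak, at 20.5, 23.9 and 18.8 kb.

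The third comparison looked at where in the genome the sites lay, among chromosomes 1 to 19 and X. Y, with 7 wild-type and 14 knockout peaks, was left out of the rankings. Wild-type peaks were densest on chromosomes 8 (9.86 per Mb, counted to the last called peak) and 11 (9.25 per Mb) and sparsest on X (3.43 per Mb). Knockout peaks were densest on X (2.45 per Mb) and sparsest on chromosome 19 (1.22 per Mb). X thus carried 3.45% of the wild-type peaks (exact 95% interval 3.18 to 3.74%) and 8.83% of the knockout peaks (8.02 to 9.68%). The ratio of wild-type to knockout peaks ran from 1.402 on X to 6.59 on chromosome 11. On X 77 of 572 wild-type peaks (13.5%, 10.8 to 16.5%) overlapped a knockout peak, against 740 of 16012 (4.62%, 4.30 to 4.96%) on the autosomes. In the other direction X did not stand out: 90 of its 408 knockout peaks (22.1%, 18.1 to 26.4%) overlapped a wild-type peak, against 21.2% (19.99 to 22.48%) on the autosomes. Among the autosomes chromosome 18 had the highest share of wild-type peaks with a knockout peak, 8.98%. With only wild-type peaks scoring at least 100, X kept the higher share, 15.8% (12.1 to 20.1%) against 6.80%. With both lists limited to such scores, which leaves 353 knockout peaks, 8 of 342 X peaks (2.34%, 1.02 to 4.56%) and 1.66% of autosomal peaks were shared, 1.41 times as many and within the counting error.

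**Figure D3:**
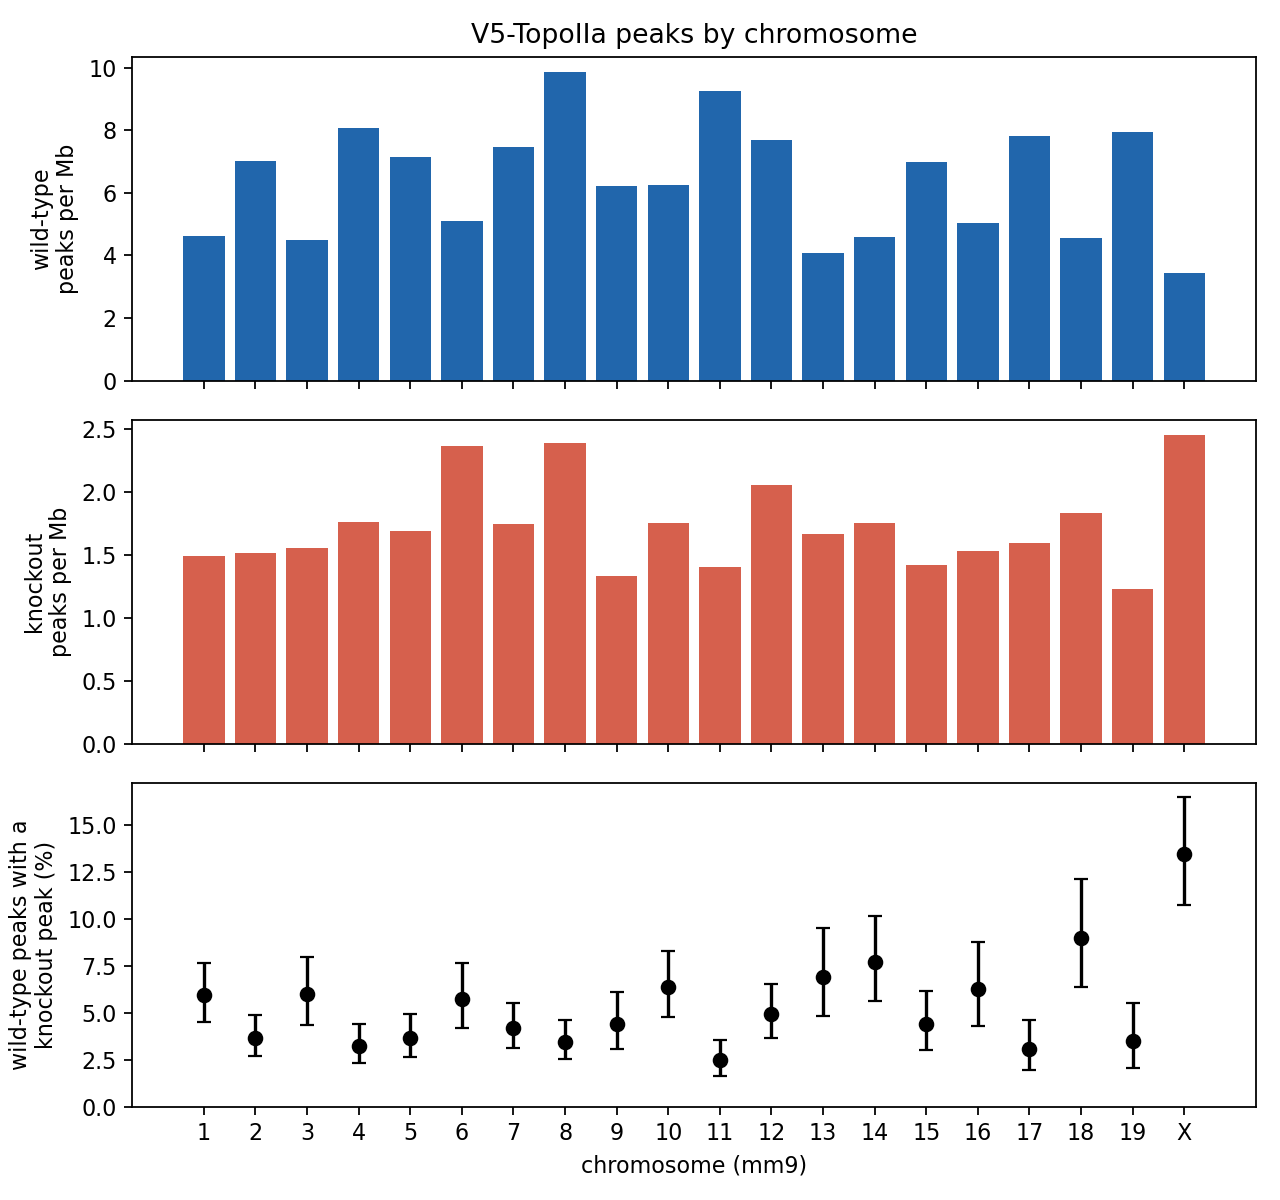
Wild-type peaks per Mb (top), knockout peaks per Mb (middle) and share of wild-type peaks that overlap a knockout peak in percent with exact 95% intervals (bottom), for chromosomes 1 to 19 and X. X has the lowest wild-type density (3.43 per Mb), the highest knockout density (2.45 per Mb) and the highest share (13.5%).

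Part of the knockout list was concentrated in a few places. Groups of at least 10 knockout peaks with gaps of at most 10 kb occurred 8 times and held 198 peaks (4.28% of the list), while 100 random placements gave no group above 5 peaks. In 4 groups, with 100 knockout peaks, every knockout peak lay on a wild-type peak. The biggest, on chromosome 8 from 126062404 to 126146830, held 59 knockout peaks inside 1 wild-type peak of 89408 bp (126059865 to 126149272, score 80.3). The other 4 groups, with 98 knockout peaks, touched no wild-type peak. Among these were 2 neighbouring groups on chromosome 6, from 47604297 to 47636413 with 35 peaks and from 47687092 to 47728279 with 30 peaks, whose nearest wild-type peaks were 58.3 and 56.4 kb away. A group of 21 on chromosome 7, from 67002330 to 67036807, lay 270 kb from any wild-type peak, and a group of 12 on X, from 72888854 to 72917402, lay 0.339 kb from one. Without the 8 groups the knockout list held 4424 peaks, of which 19.9% overlapped a wild-type peak.

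**Figure D4:**
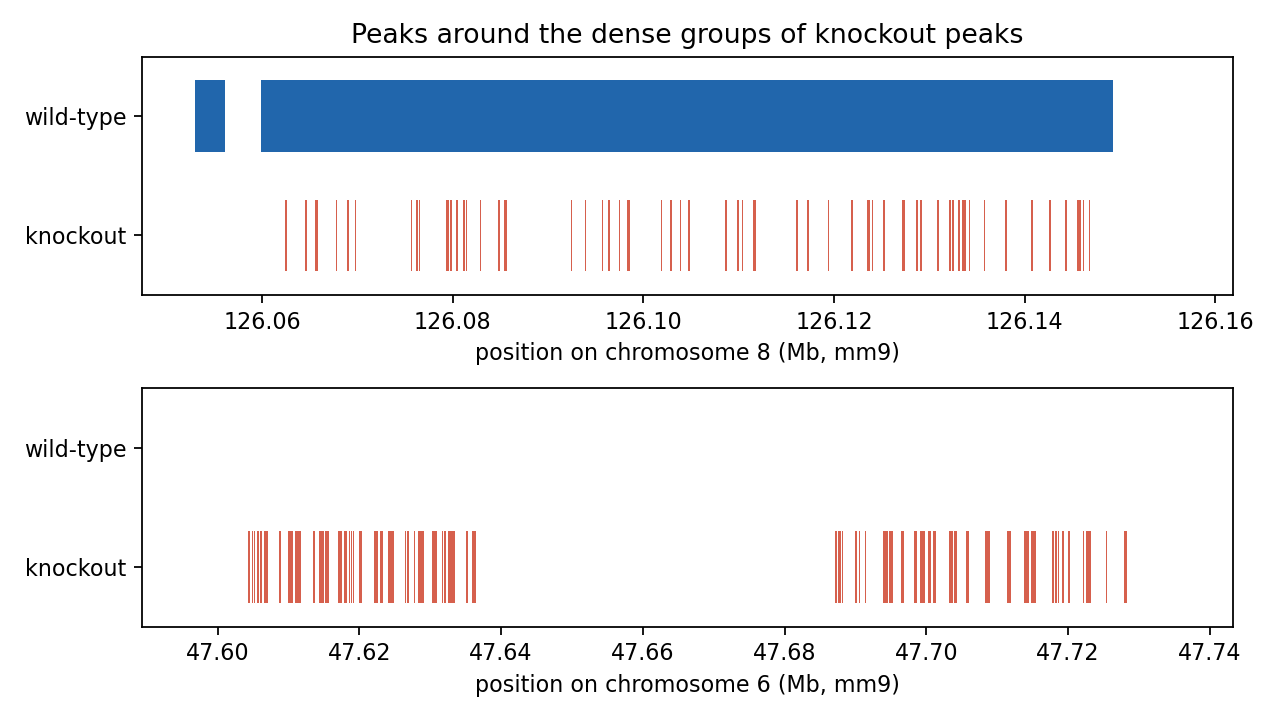
Wild-type (blue) and knockout (red) peaks, drawn to scale along mm9 positions in Mb, around the group of 59 knockout peaks on chromosome 8 (top) and the groups of 35 and 30 on chromosome 6 (bottom). The chromosome 8 group lies inside 1 wild-type peak, and no wild-type peak lies near the chromosome 6 groups.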

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

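Of 48 alternative values, 21 stayed within the counting interval of the reported value or, for numbers of peaks, within 1.5 times of it, and 27 moved. None reversed the order of the lists in number, although a score limit need not be equally strict in both lists. At scores of at least 100 and 200 the wild-type list fell to 8818 and 3541 peaks and the knockout list to 353 and 88. The share of wild-type peaks with a knockout peak (4.93%) became 0.0121% with an overlap of 50% of both peaks, which the widths almost exclude, 4.12% with centres within 500 bp or every peak set to 500 bp, 1.70% and 1.16% at scores of at least 100 and 200 in both lists, and 7.16% at a score of at least 100 in the wild-type list alone. The share of knockout peaks with a wild-type peak (21.2%) became 0.0433% with the 50% overlap, 22.6% within 1 kb, 15.3% with centres within 500 bp or every peak at 500 bp, 17.6% without peaks over 5 kb and 19.9% without the dense groups. It became 47.9% and 52.3% at scores of at least 100 and 200 in both lists, and 55.5% and 60.2% with these limits on the knockout list alone. With 5 bins the highest held 10.04% shared peaks. At equal length the share (9.22%) became 5.95% when ranked by width and 8.3% in the top 1000. At a score of at least 100 X held 3.88% of wild-type and 6.23% of knockout peaks, and its shared share (13.5%) fell to 2.34%. With the limit on the knockout list alone it fell to 1.57% (0.722 to 2.97%), against 0.993% (0.845 to 1.16%) on the autosomes. Beyond the fewer peaks that each limit leaves, the cause was not tested. No paired analysis was possible because each genotype has 1 library. Depth is unknown, so a missing knockout peak means not called at this depth and threshold.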

Other observations

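The shared share of wild-type peaks on X comes from a planned comparison, and the other tests in this part were chosen after the overlap of the lists had been seen, although for chance overlap on X and the line through the autosomal shares the prediction was written before the result.

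Wild-type TopoIIa sites came in neighbourhoods. With gaps of at most 50 kb, 4933 wild-type peaks (29.7%) stood in 469 groups of at least 5, against 3.87% in 100 random placements, and the biggest group had 97 peaks. With gaps of at most 10 kb the biggest group was on chromosome 10 from 80702210 to 80894658, with 32 peaks over 192 kb and a top score of 598. The next in size lay on chromosome 8, from 72895176 to 73035397 with 23 peaks, from 124978180 to 125120857 with 22 and from 124748126 to 124872503 with 16. In the 10 biggest of these groups 1 of 172 wild-type peaks (0.581%, exact 95% interval 0.0147 to 3.20%) overlapped a knockout peak. The shares of their chromosomes predict 7.16 and those of their score bins 9.86. Counted per wild-type peak, shared peaks were thus fewer in these groups than predicted. The groups were, however, picked for many wild-type peaks, and both predictions rise with that number. The groups were at most 192 kb long, and the autosomes had 0.230 to 0.408 shared peaks per Mb, so by length few are expected. Counting by length in turn ignores how dense the wild-type peaks were in the groups. Which way of counting applies was not tested, so a deficit is neither shown nor excluded. The knockout list, which is shorter, had 6.82% of its peaks in groups of at least 5 at gaps of 50 kb, against 0.0281% in random placements, and 2.60% without its 8 dense groups.

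Across the 19 autosomes the share of wild-type peaks with a knockout peak was lower where wild-type peaks were denser (Pearson r = -0.86, Spearman rho = -0.89, 2-sided permutation p = 1e-05 for each, the smallest that 100000 permutations can give, 2e-05 after Benjamini-Hochberg adjustment over 2 relations). Without chromosomes 8 and 13, the farthest from the median density, r was -0.87. Both measures contain the wild-type count, which by itself produces a negative relation. The number of shared peaks per Mb, which does not divide by that count, ran from 0.230 to 0.408 and showed no relation that passed the test (r = -0.21, permutation p = 0.38, rho = -0.29, permutation p = 0.23, both unchanged by the adjustment, and r = -0.40 without the same 2 chromosomes). For X the autosomes predict 0.323 shared peaks per Mb (95% prediction interval 0.2004 to 0.4452), and X had 0.462 (counting interval 0.370 to 0.568), above the prediction interval by less than its counting error. The line through the shares predicts 7.71% for X (5.54 to 9.88%). X had 13.5%, above that interval, so by the prediction written beforehand X did not follow the autosomal line. No conclusion was drawn from that outcome, because the wild-type count is in both measures. At 3.43 wild-type peaks per Mb, X was sparser than every autosome (lowest 4.08, on chromosome 13). Both predictions for X thus extend the lines beyond the autosomal densities. Chromosomes are not replicates.

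The first pattern is the low overlap of the wild-type list with the knockout list. Narrow knockout peaks that miss nearby wild-type peaks do not account for it, because setting every peak to 2 kb hardly changed the overlap. The shared share of wild-type peaks was then 5.21% (exact 95% interval 4.87 to 5.56%), against 4.93%. That share has a ceiling, since the knockout list holds 4622 peaks for 16591 wild-type peaks. The share of knockout peaks on a wild-type peak has no such ceiling, and went from 21.2% to 20.2%. The 2 kb width also shortens wider wild-type peaks, so that change mixes gains and losses. Counting knockout peaks within 1 kb of a wild-type peak shortens none, and gave 22.6%. Nor is the knockout list a plain subset of the wild-type list, since 55.5% (50.2 to 60.8%) of knockout peaks scoring at least 100 lay on a wild-type peak. The line set for a thinned sample, over 90%, was written after the overlap had been seen. A thinned sample with other calls added would also fall below that line, so thinning itself is not excluded. A knockout library of lower enrichment or depth, or called with other settings, as its narrow peaks leave possible, cannot be told apart from a loss of TopoIIa activity without Brg1: 27% of the 100 highest-scoring wild-type peaks were shared, and 1 library per genotype without its reads leaves all of these open. The gradient with score may arise under each.

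The second pattern is the dense groups of knockout peaks. A wide region called whole in the wild-type library and in pieces in the knockout library does not account for all of them. The reason is that 4 of the 8 groups, with 98 knockout peaks, touched no wild-type peak. Of all knockout peaks in the groups 50.5% lay on a wild-type peak, where the line set was over 90%. Its exact 95% interval (43.3 to 57.7%) treats peaks as independent, but each group was wholly on or wholly off wild-type peaks. It may apply to some of the 4 groups on wild-type peaks: 59 knockout peaks lay on 1 wild-type peak, and the other 41 on 5, or 8.2 for each, although one of these groups, with 16, spread over 3. Repeated sequence or a copy-number difference was not tested for any group, because neither the reads nor the mm9 sequence were used here. No biological explanation was tested.

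The third pattern is the higher shared share of wild-type peaks on X, 13.5% (10.8 to 16.5%) against 4.62% on autosomes, which knockout peaks do not show (22.1% on X, 21.2% on autosomes). Wild-type score does not account for it: X was higher in 10 of 10 wild-type score bins. The autosomal shares at equal wild-type scores predict 27.0 shared X peaks where 77 were found. Knockout score was not matched in this way. With only knockout peaks scoring at least 100, 1.57% (0.722 to 2.97%) of X peaks and 0.993% of autosomal peaks were shared. That gap was within the counting error. The share also divides by the wild-type count, which is low on X. By shared peaks per Mb X had 0.462, little above the autosomal prediction interval (0.2004 to 0.4452), which for X reaches beyond the autosomal densities. Chance meetings with the denser knockout peaks of X gave a mean of 3.22 and at most 13. Why X has few wild-type peaks for its knockout peaks, 1.402 for each, was not tested, and an effect of genotype on X stays open as untested.

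Tied scores were more common in the knockout list, with 1445 distinct values among 4622 peaks (31.3%), against 10525 among 16591 (63.4%) in the wild-type list. The knockout scores also lay closer together (interquartile range 54.2 to 66.8 against 70.0 to 180.48). Whether that range alone gives the ties was not tested. Within 10 kb of a wild-type peak but not on one lay 599 knockout peaks (13.0%), against a mean of 482.6 after random placement, 1.24 times as many. Both counts are out of all 4622 knockout peaks. Of these 982 lay on a wild-type peak, against a mean of 74.45 after random placement. Fewer observed peaks were thus left to lie nearby, so 1.24 understates the excess.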
